A study of Teleopsis quinqueguttata with 28 samples.

How the data were processed

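Samples were total RNA from pools of female or male eye-antennal discs of *Teleopsis quinqueguttata*. Per the labels' protocols, messenger RNA was amplified with T7 polymerase before labelling, and the samples of a pair were labelled with Cy3 and Cy5 in alternation with regard to sex. The 14 arrays carry 37823 spots each, of which 1417 are controls; the others are 18203 probes of 60 bases in 2 spots each. The species from which the probe sequences were designed is not given in the sources used here.

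Per the file headers, the scanner output gives spot and local background intensities on a linear scale for each channel, with flags for spots well above background, saturated or outlying, and a processed intensity from which background was subtracted and in which the dyes were normalized within the array. The headers name Agilent Feature Extraction 9.5.3.1 for slides 2 to 5 and 10.5.1.1 for slide 6, whereas the submitters' processing notes name version 8.5.1.1. Both samples of an array were deposited with the same scanner output, and each sample's values were read from its own channel, taken from the dye label. The deposited value table holds log2 values from the authors for 3748 rows numbered without names. Its scale was found by setting it against the scanner output. With probes joined by their name up to its last point, 3655 rows equalled the log2 of the mean processed intensity of the unit's spots within a root mean square of 0.01 over 28 samples, and each of the 28 columns lay closest to its own sample's channel. Joining probes by the name before the probe number matched 3503 rows, and by the name before the colon 3621. The table is thus on a log2 scale, per channel and not centred, with no sign to settle; how the authors treated the unmatched rows is not known. The medians of its columns for replicates 1 to 14 were 9.19, 8.99, 8.03, 8.39, 7.89, 7.95, 8.75, 8.51, 8.74, 8.75, 8.53, 8.34, 8.42 and 7.21 in females. In males they were 9.24, 8.99, 7.94, 8.44, 8.02, 7.90, 8.81, 8.60, 8.70, 8.75, 8.54, 8.33, 8.44 and 7.26.

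From the spot intensities, background was corrected with the normexp method (offset 50) in limma 3.58.1 under R 4.3.3, and log ratios were normalized by loess within each array with control and outlier spots at weight 0. Control spots were then removed, and outlier-flagged spots (at most 9 per sample) were left out. Spots of a probe were averaged. A probe entered when all its spots were well above background in at least 7 female or at least 7 male samples, in the channel of that sex. Probes of a transcript unit were averaged; a unit had a median of 4 probes, and 354 units rested on 1. The unit rule was taken from the match to the deposited table. The offset draws ratios of dim probes toward 0. Levels are single-channel log2 values after loess and Aquantile normalization between arrays.

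Ratios were turned to male minus female and fitted with lmFit and eBayes, with a dye intercept per unit. P-values were adjusted by the Benjamini-Hochberg method over all 3419 units and called at 0.05, two-sided. The array is the block in this design, since the female and male samples of a number shared an array per the labels. Deviations of the samples of one array from their group means correlated at -0.22 to 0.97. The median was 0.49, with 13 of 14 arrays above 0.1, against a median of -0.07 for samples of different arrays. On 4 of 14 arrays the samples correlated best with each other. Both levels of an array are computed from the average log intensity of the same spots. Part of this correlation is thus built in, and it does not test the pairing. Slide by sex terms were tested with limma's F test, and the slide was also entered as a random block and as a dye by slide term. The direction of calls was tested with a two-sided exact binomial test.

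The spike-in signal over background in the Cy5 channel was 1.35 to 1.78 on slide 6 and 53.5 to 104.9 on slides 2 to 5. The spots well above background per sample ranged from 48.9% to 75.6%, and median spot intensities from 34.5 to 281.0.

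The steps were tested on simulated data made from residuals of the 3419 units, with sex relabelled within arrays and 200 units changed. Over 10 such sets, the test found 69.9% of units changed by 1.2-fold, 95.7% of those changed by 1.5-fold and 99.5% of those changed by 2-fold. These shares are for 200 changed units, and the Benjamini-Hochberg method admits larger p-values when many units change. Small folds would thus be found less often where few units change, as with the 14 calls in the data. A median of 3 unchanged units per set were called, but 213 were in 1 set, and 12.7% of all calls were of unchanged units. Effects of 2-fold were found for 99.8% of units given a dye effect. Slide by sex effects were found for 98.2% of the units that were given them. These raised the sex ratio 2-fold on some slides and lowered it 2-fold on the others, so slides differed by more than 2-fold. The 98.2% is thus not the share that would be found if slides differed by only 2-fold.

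The unnamed units described in the text were fixed before the data were examined as at most the 2 largest each way among those that passed the test with the sign of the mean on at least 12 of 14 arrays; any other is said to be chosen after its values were seen. The 32 gene lists fixed in advance use fruit fly gene symbols and were not tested, because the files used here do not pair probes with gene names. Alternatives covered background correction, normalization within and between arrays, filters, the summary over probes, the dye term, array weights, the pairing, slides, left-out arrays, the deposited table and an ordinary test. Probe sequences of called units were set against all probes with blastn 2.17.0. The first component of the ratios was computed by singular value decomposition. Differences between probes of a unit were tested with limma's diffSplice.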

Results

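Gene expression was compared between female and male larvae of the stalk-eyed fly *Teleopsis quinqueguttata*, a species whose sexes carry eye stalks of similar length. The tissue was the eye-antennal disc, the sheet of larval cells that forms the adult eyes, antennae and much of the head capsule. Discs came from wandering larvae of the last larval stage, and each RNA sample was a pool of 25 pairs of discs per the source label. The labels' growth protocol gives 25 eye discs, and the tissue label names brain beside the disc, so the share of brain tissue in the pools is open. There were 14 female and 14 male samples, numbered 1 to 14 in each sex, and the female and the male sample of a number were hybridised together on 1 of 14 two-colour arrays. Males carried Cy5 on 7 arrays and Cy3 on the other 7. The arrays lay on 5 slides of 2 or 4 arrays, and every slide held both dye orientations equally often. Adult heads, which the series text also names, were not analysed here.

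Signal varied between arrays. Between 48.9% and 75.6% of the spots of a sample were well above background, with a median of 68.9%. Both samples of replicate 14 were the dimmest of slide 6, with 48.9% of spots well above background in the female and 57.7% in the male. No spot was saturated. Of the 18203 probes, 12693 (69.7%) were well above background in at least 7 samples of one sex and were tested. They represent 3419 transcript units, that is, groups of probes that share a name up to its last point, out of 3791 on the array. The files do not pair these units with gene names, so units are reported by the identifier in the probe names, with the probe sequences of those that are described. The number of arrays limits the precision. The labels call the samples biological replicates.

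The first question was which transcripts differ in level between female and male discs in this sexually monomorphic species. Very few did. Of 3419 units, 14 (0.409%) passed an adjusted p of 0.05 in limma's moderated test of the male over female ratio, and 13 of these 14 were higher in females. Differences were small, and only 2 units differed by at least 1.5-fold, both higher in females. The 1 unit higher in males was 1.39-fold higher. The share of calls higher in males was 7.14% (exact binomial 95% interval 0.181 to 33.9%), which differed from an even split (two-sided exact binomial test, p = 0.00183), although units are not independent of one another. Among the 340 units with an unadjusted p under 0.05 (171 would be expected by chance), 183 were higher in males and 157 in females. This balance turned in other fits, for example to 129 in males and 193 in females with scaling between arrays. The count itself moved too, to 139 without slide 6 and 565 without replicate 3, and it was not set against relabelled arrays. With the scanner's processed signals in place of the corrected spot intensities, 5 of 19 calls (26.3%) were higher in males, which did not differ from an even split (exact binomial p = 0.0636), and with array weights 24 of 60 (40%) were (exact binomial p = 0.155). Differences of at least 1.5-fold were called for 11 units with the processed signals and for 13 in the deposited value table.

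The largest difference was that of unit 3532252:1, which was 1.77-fold higher in female discs (95% interval 1.65 to 1.90; limma, adjusted p = 1.29e-07). Its male minus female difference was -0.82 on the log2 scale (SE 0.047), and females were higher on 14 of 14 arrays. Its mean level was 10.89 ± 0.80 in females and 10.06 ± 0.73 in males (log2, SD, n = 14 each), so single-channel levels varied over the arrays about as much as the sexes differed. Of its 5 probes, 1 was not well above background in any sample and was left out. The probe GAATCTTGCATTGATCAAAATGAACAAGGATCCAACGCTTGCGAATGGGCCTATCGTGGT gave -0.92 (SE 0.060), the probe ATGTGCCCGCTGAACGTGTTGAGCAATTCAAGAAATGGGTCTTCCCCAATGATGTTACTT gave -0.91 (SE 0.055), and the probe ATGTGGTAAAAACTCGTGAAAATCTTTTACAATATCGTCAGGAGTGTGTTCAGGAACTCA gave -0.95 (SE 0.049). The remaining probe, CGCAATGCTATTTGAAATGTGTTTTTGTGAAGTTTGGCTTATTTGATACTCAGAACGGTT, was well above background in 10 female and 10 male samples only and gave -0.51 (SE 0.099). Within slides, the mean difference of the unit lay between -0.64 (slide 2) and -1.02 (slide 3).

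Unit 3532011:1 was 1.74-fold higher in females (95% interval 1.56 to 1.94; limma, adjusted p = 5.4e-05), a log2 difference of -0.80 (SE 0.075) with females higher on 14 of 14 arrays. Its mean level was 9.61 ± 0.37 in females and 8.81 ± 0.36 in males (log2, SD, n = 14 each). All 5 of its probes were well above background in every sample and differed between the sexes by -0.72 to -0.94. The probe with the largest difference was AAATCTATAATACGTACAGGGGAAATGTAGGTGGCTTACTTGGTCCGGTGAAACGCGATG, at -0.94 (SE 0.055), and that with the smallest was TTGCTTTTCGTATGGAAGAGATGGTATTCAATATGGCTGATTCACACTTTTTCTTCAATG, at -0.72 (SE 0.084). Its means within slides ran from -0.73 (slide 2) to -0.90 (slide 3).

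**Figure D1:**
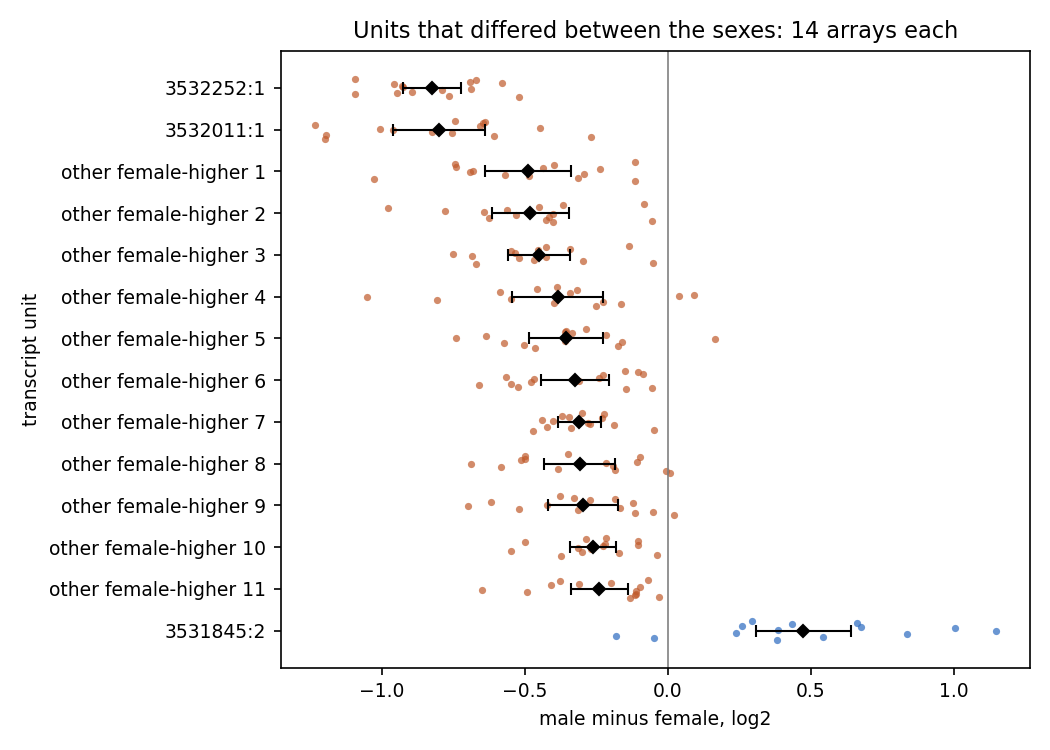
Male minus female log2 ratio (x axis) of the 14 transcript units that differed between the sexes (y axis), with each of 14 arrays as a point and the mean with its 95% interval as a black diamond and bar. Units higher in females are brown and the unit higher in males is blue; 3532252:1 and 3532011:1 lie below 0 on 14 of 14 arrays, and 3531845:2 lies above 0 on 12 of 14.

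Only 1 unit was higher in males. Unit 3531845:2 was 1.39-fold higher in male discs (95% interval 1.24 to 1.56; limma, adjusted p = 0.00955), a log2 difference of 0.47 (SE 0.077), with males higher on 12 of 14 arrays. Its mean level was 11.19 ± 0.69 in males and 10.72 ± 0.62 in females (log2, SD, n = 14 each). All 5 probes were well above background in every sample and gave 0.40 to 0.54. The largest was that of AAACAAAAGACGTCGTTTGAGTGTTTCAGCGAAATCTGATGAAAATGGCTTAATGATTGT, at 0.54 (SE 0.089), and the smallest was that of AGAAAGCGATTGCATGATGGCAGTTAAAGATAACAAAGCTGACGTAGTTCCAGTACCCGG, at 0.40 (SE 0.088). Its means within slides were 0.17 (slide 2, SD 0.304) and 0.18 (slide 3, SD 0.513) over 2 arrays each and up to 0.80 (slide 5, SD 0.341) over 4 arrays, a variation that did not pass the slide by sex test. Its call was lost when slide 4, 5 or 6 was left out (adjusted p = 0.0699, 0.178 and 0.149) and with a dye term for each slide (adjusted p = 0.077). It was lost too with median centring in place of loess (limma, adjusted p = 0.207) and when the array was ignored.

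The other 11 units that passed the test were all higher in females, by 1.18-fold to 1.40-fold, with adjusted p-values from 0.000289 to 0.0346. Of these 11, 7 were higher in females on all 14 arrays, and each was higher in females on at least 12. Their mean levels in females ran from 7.3 to 9.3 on the log2 scale. In all 14 called units, every probe tested had the sign of the unit's mean, and 1 of the 14 rested on a single probe.

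**Figure D2:**
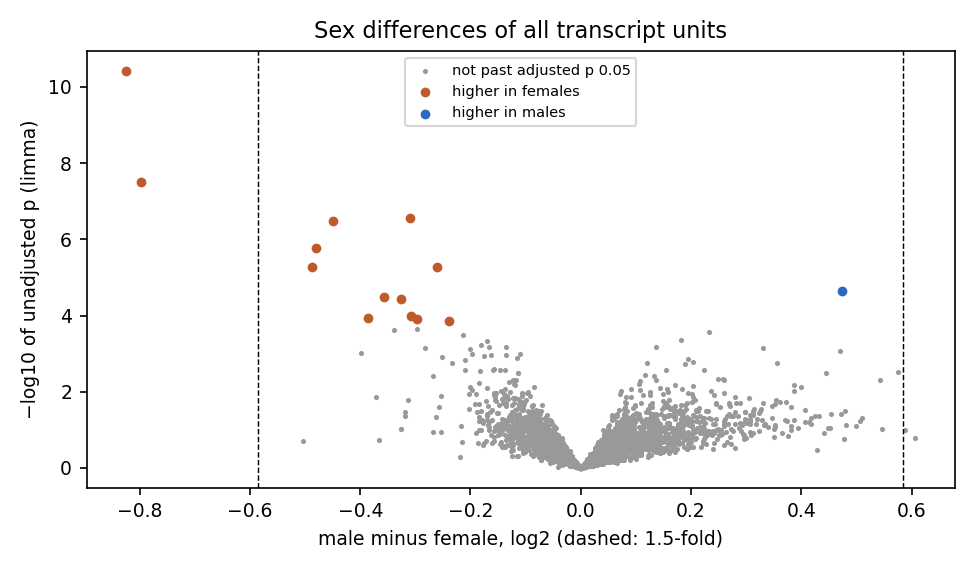
Male minus female log2 difference (x axis) against the negative log10 of the unadjusted p from limma (y axis) for each of 3419 transcript units. Brown points are the 13 units higher in females, the blue point is the 1 unit higher in males, grey points did not pass an adjusted p of 0.05, and dashed lines mark 1.5-fold, which 2 called units exceed.

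The data also bound the sex differences of the tested units, as ratios after this processing. The 95% interval of the sex difference lay within 1.5-fold in both directions for 3302 of 3419 units (96.6%), and within 2-fold for 3407 (99.6%). These intervals are not adjusted for the number of units. When units were put into 4 equal groups by mean level, 99.5% of the dimmest group and 91.5% of the brightest had an interval within 1.5-fold. The offset of the background correction draws ratios of dim probes toward 0, so the narrow intervals of dim units bound the ratios as computed and not the transcripts themselves. Brighter units may be affected too. In the scanner's processed signals, which carry no offset, 3532011:1 gave -0.94 on the log2 scale against -0.80 here. With those signals 11 units were called at 1.5-fold or more, against 2 here. In the brightest group, 5 units were called higher in females and 1 in males. The dimmest group held 2 calls, both higher in females. Detection gave no sign of transcripts limited to one sex. There were 0 probes that were well above background in at least 12 of 14 samples of one sex and at most 2 of 14 of the other. The largest excess for any probe was 7 male samples over female samples, and 4 female samples over male samples.

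The number of calls depended on how slides were treated. With a separate dye term for each slide, 7 of the 14 units were still called, all higher in females, and leaving out slide 3, 4, 5 or 6 left 8, 7, 7 and 7 calls. Leaving out slide 2 gave 16 calls. With the slide as a random block the same 14 units were called, but that fit put the correlation within slides at -0.095, so it took up no shared slide variation. Both units above 1.5-fold were called in each of these fits. When the array was ignored, and single-channel values were compared without the pairing, 5 units were called, none of them higher in males, and 3532252:1 was not among them (adjusted p = 0.94).

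Whether the sex difference itself changed between slides was tested with a slide by sex term. In limma, 0 of 3419 units passed an adjusted p of 0.05, and 38 had an unadjusted p under 0.05. These are fewer than the 171 expected by chance, so the test was conservative and may have missed small changes between slides. A difference between the dyes that remained after loess was called for 1 unit, and 198 units had an unadjusted p under 0.05 in that test.

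Male over female ratios varied widely from array to array. The SD of a unit's male minus female ratio over the 14 arrays had a median of 0.208 on the log2 scale. On single arrays, between 2 (replicate 2) and 226 (replicate 7) units differed by 2-fold or more between the female and the male pool. Replicates 5 and 7 had the widest ratios, with SDs over units of 0.454 and 0.520. The ratios of different arrays correlated over units at anything from -0.66 to 0.76, and 42 of the 91 pairs of arrays correlated below 0 after every array had been turned to male minus female (units are not independent replicates). A single axis held 49.9% of the sum of squares of all ratios, and 8 arrays scored above 0 on it and 6 below. In raw signals without background correction or loess, with array medians and dye means removed, the first axis held 47.2%, but its array scores correlated with these at 0.23 in size. Of 50 units with the most variable ratios, 39 correlated with this axis at 0.7 or more in size. Altogether 12 units had an SD of at least 1 on the log2 scale, and none of these was among the 14 called units.

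**Figure D3:**
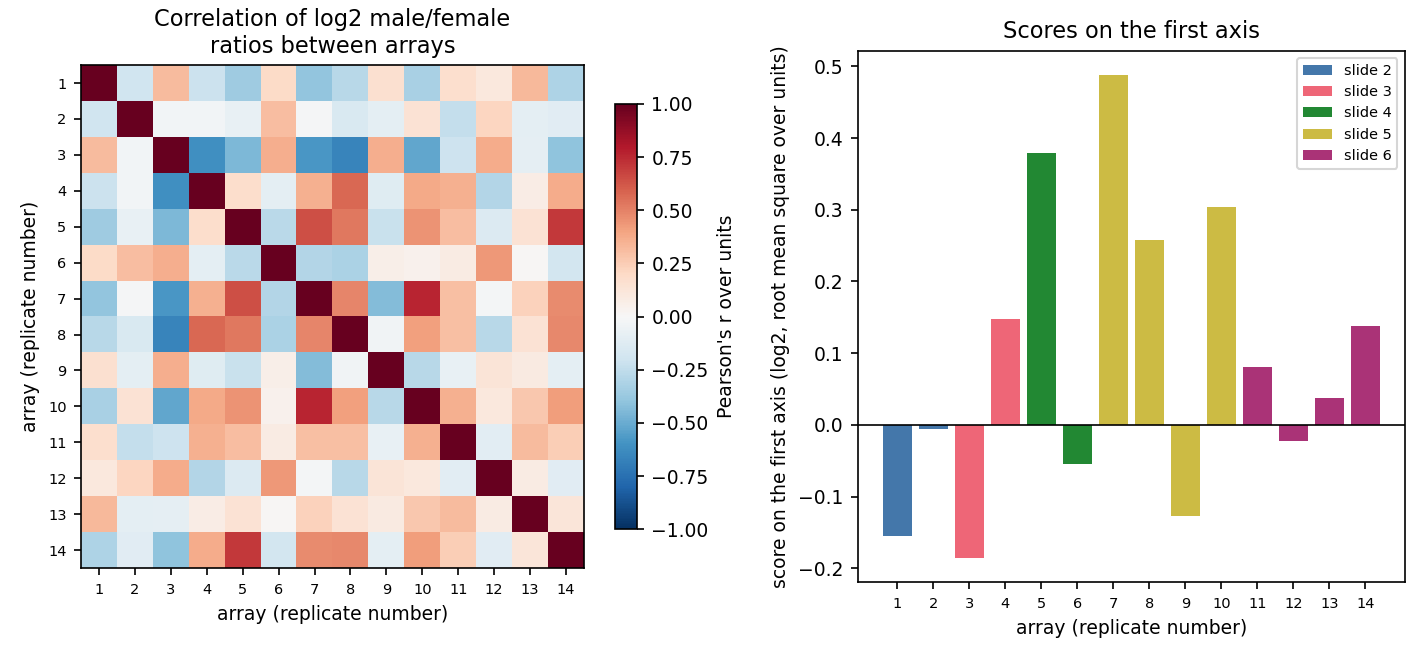
Left, Pearson correlation over 3419 units of the male minus female log2 ratios of each pair of the 14 arrays (both axes, by replicate number), on a colour scale from -1 to 1. Right, score of each array (y axis, log2) on the axis that held 49.9% of the sum of squares, coloured by slide; 8 arrays lie above 0 and 6 below, and slides 3, 4, 5 and 6 have scores of both signs.

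The most variable unit was 3532894:1, chosen here after its values were seen. Its male minus female ratio ran from -3.53 to 4.30 on the log2 scale. On replicate 3 its level was 12.22 in males and 7.92 in females, and on replicate 2 it was 10.43 in males and 13.96 in females (log2). All 5 of its probes swung in this way, the probe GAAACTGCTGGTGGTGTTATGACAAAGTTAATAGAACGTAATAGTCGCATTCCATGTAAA from -4.04 to 4.43. On the arrays with the widest gaps, replicates 2, 3, 4, 9 and 10, the sample in Cy5 was the higher one each time. On replicates 7, 8, 12, 13 and 14 the sample in Cy3 was higher, by smaller gaps. The swings thus cannot be read as differences between the pools alone. Averaged over the 14 arrays, the sexes differed by -0.04 (SE 0.51), which did not pass the test (limma, adjusted p = 0.974).

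**Figure D4:**
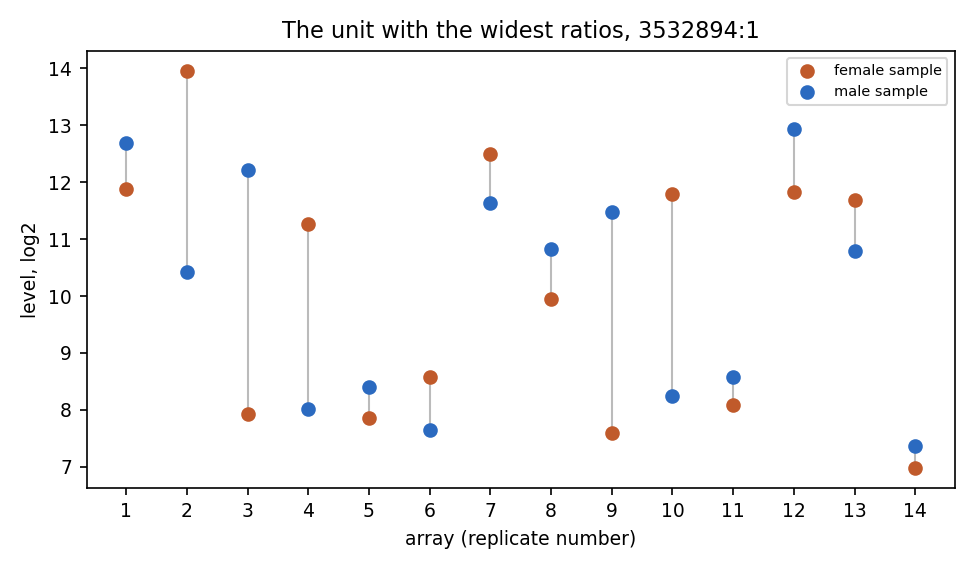
Level of unit 3532894:1 (y axis, log2, after normalisation of single channels) in the female (brown) and male (blue) sample of each array (x axis, replicate number), joined by a grey line. The higher sex changed from array to array, with the widest gaps on replicates 2, 3, 4, 9 and 10, on each of which the sample in Cy5 was the higher one.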

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

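Joining probes by contig, the covariate and the fit without replicates 5 and 7 were chosen after seeing the data; the gene list tests were not run, for want of gene names. Both female-higher units above 1.5-fold kept their sign in every fit that held them. The 3532011:1 call held in all of them (log2 -0.999 to -0.66; largest adjusted p 0.0105). The 3532252:1 call ended only with no replicate block (adjusted p = 0.94, with SE 0.279 in place of 0.047), where 5 units were called in all, 0 higher in males and 5 in females, 1 of them by 1.5-fold (0% male, exact binomial p = 0.0625), since that fit adds the spread of levels over arrays to the error. The 3531845:2 difference stayed above 0 (0.34 to 0.56) but lost its call in 6 fits. The cause of the following changes was not tested unless stated.

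Calls, with those higher in males and in females, numbered 29 (6 and 23) without background correction, 19 (5 and 14) with scanner processed signals, 6 (0 and 6) with median centring, 27 (2 and 25) with scaling between arrays, 26 (5 and 21) with only probes well above background in all samples, 53 (9 and 44) over single probes, 17 (2 and 15) with no dye intercept, 60 (24 and 36) with array weights, 7 (0 and 7) with a dye by slide term, and 8 (1 and 7), 7 (0 and 7), 7 (0 and 7) and 7 (0 and 7) without slides 3, 4, 5 and 6. They numbered 30 (5 and 25) in the deposited value table, 26 (2 and 24) with the first component as a covariate and 12 (3 and 9) without replicates 5 and 7. Leaving out 1 replicate gave 10 to 19 calls, 1 to 3 higher in males and 9 to 16 in females, with 3 higher in males without replicate 1 or 7 and 2 without replicate 2. Of the 14 units, all were called without background correction, with the stricter filter and with the covariate, 13 in the deposited table, 10 with processed signals and 6 with median centring.

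The female share stayed above that of males throughout. The percent higher in males no longer differed from an even split with processed signals (26.3%, p = 0.0636), array weights (40%, p = 0.155), without slide 3 (12.5%, p = 0.0703) and without replicates 5 and 7 (25%, p = 0.146); it was 20.7% without background correction, 19.2% with the stricter filter and 5.88 to 18.8% leaving out 1 replicate. Array weights ran from 0.237 (replicate 7) to 7.48 (replicate 2), and with sex relabelled within arrays that fit called up to 86 units, in 4 of 30 relabellings; the fit without weights called 0 in those 30 but up to 26 in a separate draw of 100.

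Units called at 1.5-fold or more numbered 11 with processed signals, 13 in the deposited table, 4 with the stricter filter, 12 single probes, 4 with array weights and 2 leaving out any 1 replicate. Dye effects numbered 6 without background correction, 0 with processed signals, 2078 with median centring, which leaves intensity-dependent dye bias in place, 22 single probes, 63 with array weights, 8 with slide as a random block, 2 without slide 2, 0 without slide 4, 5 or 6, and 1 to 2 leaving out 1 replicate. No alternative called a unit whose ratio varied among slides (limma; 10 to 195 at an unadjusted p under 0.05). Signal over background was lowest in replicate 14 (48.9% of spots well above background in the female), without which 10 units were called.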

Other observations

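The tests of the shared axis (except that of loess) and of the sex calls against relabelled arrays were chosen after those results, or other relabellings, were seen; those of shared probes, of loess, of the dye call and of the dim probes in processed signals were written down before, that of loess in place of one on the first axis of raw signals that had not decided, and the last in place of a filter on dim probes that had been run first and that removes the probes in question by its construction.

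Sex was relabelled within arrays with 7 arrays each way, in 100 ways including the real one. At least 14 calls came in 2 of the 100, the real one among them (highest other 26). At least 13 in one direction came in 2 (highest other 17). At least 2 calls at 1.5-fold came in 1, the real one (highest other 0). These counts argue against chance at the 0.05 level, over the 100 ways drawn and not all possible ones. The other ways were drawn without regard to slide, whereas the real labels are balanced on every slide. They thus do not keep to the design, and the comparison is approximate. At least 1 call, as in males, came in 2 (highest other 26). The last is a count over all units and does not test the unit called in males, whose call was lost in 6 alternatives. One relabelling called more units than the real one, which points to a structure of the samples. For the dye, 2 of 100 relabelled orientations, the real one among them, gave at least 1 call (highest other 931). This passes the 0.05 level, but any single call would pass it, so it does not show that the 1 dye effect is real. Relabelled orientations can thus align with a structure of the arrays, and whether the 1 real call comes from it was not tested.

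Of the 14 called units 13 were higher in females, although the species is monomorphic in its eye stalks. Probes shared between the called units do not account for this: 0 of the 13 units had a probe aligned over 40 or more bases to a probe of another. The shared axis of the arrays is argued against as the whole cause, because 92.3% of calls were higher in females with the axis as a covariate (24 of 26, exact binomial p = 1.05e-05). A part of it stays open, since without replicates 5 and 7, which had the highest scores on the axis, 3 of 12 calls were higher in males (25%, exact binomial p = 0.146) and 9 of the 14 units were called. What stays open besides is sex itself, which the design names and which was not tested further, the centring, which could not be tested because loess sets the ratios of each array around 0, and the small number of calls, since the share higher in males reached 40% with array weights.

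One axis held 49.9% of the sum of squares of the male minus female ratios, against at most 21.2% in 20 draws with signs set at random for each unit and array. Sex as the source is argued against, as only 8 of 14 arrays shared the commoner sign. Loading and mean level correlated at 0.03 (Spearman). This does not decide on the signal level, because loess removes the trend of the ratios on level within each array beforehand. Background correction is argued against by 48.5% on the first axis without it (score correlation 0.99). In ratios with only array medians removed, 98% of the length of the axis was there, read along the same unit loadings (score correlation 0.94). This does not decide on loess. Loess takes away only a trend on level, and loadings computed after it carry little of that trend. A high share was thus largely fixed in advance. With neither step and with dye means removed, the first axis held 47.2% (52.5% with both) but was another one (score correlation 0.23 in size), so the axis is not the leading one in raw signals. Different probes of a unit moved together on an array (mean intraclass correlation 0.76), so noise of single spots is not the main source. Differences between pools in larval stage, tissue share, RNA quality or amplification may underlie it and were not tested, since the labels give none of them and the units have no names.

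Within a unit, probes differed in their sex difference for 1 of 3065 units (limma's diffSplice F test, adjusted p = 5e-09; next 0.14). With sex relabelled, at most 1 unit passed in 30 relabellings, which equals the real count, so that count lends the result no weight. The unit that passed with the real labels was 3532554:1, chosen after its values were seen, a female-higher unit in which 3 bright probes gave -0.40 to -0.55 and 2 dim ones, well above background in 19 and 16 of 28 samples, gave -0.12 and -0.03. The compression of dim probes may account for part of this difference between probes. In the scanner's processed signals, which carry no offset, the dim probes reached 55.5% of the bright ones (-0.31 against -0.56), where they stood at -0.07 against -0.47 with the offset. In the processed signals the dim probes gave -0.358 (SE 0.13) and -0.263 (SE 0.091), and the bright ones -0.545 to -0.57 (SE 0.059 to 0.077). The gap that remained was not tested. Over the probes well above background in all samples, 0 of 2175 units passed (11 at an unadjusted p under 0.05). For 3532554:1 this decides nothing, because that filter removes its 2 dim probes. A transcript form that differs between the sexes was not excluded for the remainder.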
